A study of Mus musculus with 2 samples.

How the data were processed

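H3K4me3, a histone mark of active and poised promoters, was profiled by CUT&RUN in prospermatogonia, the male germ cells of the fetal testis. The cells were sorted on an Oct-GFP reporter from mouse embryos at E17.5, and 130000 cells went into each assay. In CUT&RUN an antibody directs a nuclease to chromatin, and the released fragments are sequenced. The labels give 1 H3K4me3 library and 1 IgG library, with no replicates. A peak list of the H3K4me3 library was analysed, and values of the IgG library were not used here.

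Per the submitters' processing notes, Trim Galore, Bowtie2 2.5.0, SAMtools 1.16.1, bedtools 2.27.1, MACS2 2.1.0 and deepTools 3.5.1 were used, with the mouse build mm10 and the yeast build sacCer3. Roles and settings of these tools are not given in the sources used here. The authors deposited a list of peaks with a fold enrichment at the summit, which is a ratio of fragment pileup to the local background of the peak caller. The deposited list also holds the −log10 p and −log10 q of each peak, and a score. This deposited score equalled 10 times the −log10 q without its decimals in 99.999% of peaks. These values belong to single peaks and were used only to describe, rank or filter peaks within the list.

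The whole-number pileup and the background of each summit were recovered from the fold and the −log10 p. The fold was taken as pileup plus 1 over background plus 1, and the p as the upper tail of a Poisson distribution. Pileups up to 2000 were tried, and 135053 of 135064 peaks were solved within 0.0001 of their −log10 p. The lowest background, 2.11 fragments, was shared by 41978 peaks. All 93075 higher backgrounds lay within 0.05 steps of a whole multiple of a step of 0.0158 fragments. That step is the smallest peak width, 158 bp, divided by 10000 bp, with no factor for a second library of another depth. Peak names in the list carry the letters of an IgG control, but such values arise where a 10 kb window of the H3K4me3 library itself sets the background. Reads were not used here, so this was read from the list alone. The fold is therefore read here as enrichment over the surroundings of a peak in the same library, and no subtraction of IgG signal is assumed. The total number of fragments is not given in the sources used here.

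The gene table used was of assembly GRCm38.p6, the same build as mm10, with 49943 genes on the 19 autosomes, X and Y, of which 21887 are protein-coding. It gives the start and end of each gene without strand, and no genome sequence was used here. Start sites could not be told from 3′ ends, so both ends of each gene were used in place of transcription start sites. A gene was called marked where a peak with −log10 q of at least 2 overlapped the 1000 bp either side of an end. That threshold removed 0 peaks. The level of a gene was the highest fold among those peaks, and unmarked genes, which can hold peaks away from their ends, counted as 0 in the median fold of a list. That highest fold can lie at either end, so it need not be the level of the promoter. Promoter CpG classes, CpG matching, repeat content and the use of only the 5′-most start site had been planned and were not run.

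Background shares came from the same windows moved by 100 kb. Each of 18 gene lists with 385 members in all, fixed before the data were examined, was set against 10000 random lists of protein-coding genes. These were matched on gene length in 5 bins and on another protein-coding gene end within 5 kb, a matching chosen after the data were seen. Some members of the imprinted lists are noncoding RNA genes, and Dnmt3c is listed as a pseudogene. Percentiles among random lists describe this library only. Peaks were joined over gaps of up to 1000 bp into domains, and the widest 5% were called wide. Distal peaks had their summit over 5000 bp from an end of any annotated gene.

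Shares have 95% Wilson intervals, pileups and folds have 95% exact Poisson intervals, and ratios of medians have 95% bootstrap intervals from 1000 draws. Fragments carry no molecular identifiers here, so intervals cover counting error only. With 1 library there was no test between groups and no p-value. The named genes were, by a rule fixed beforehand, the 3 members of each list with the highest fold and up to 3 unmarked members in alphabetical order. All members of the imprinted lists, the 10 protein-coding genes of highest fold, genes in the 10 widest domains and the 5 distal peaks of highest fold were added. A housekeeping gene that this rule names is not reported here. Other genes named were chosen after their values were seen. Alternatives covered stricter peaks, other windows and overlaps, join gaps and distances. The scripts were tested on simulated data: all 200 planted genes among 21887 were called, with 0 extra. Planted genes had no other protein-coding gene end within 5 kb, so calls borrowed from a neighbouring gene were not tested. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.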

Results

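H3K4me3 was mapped by CUT&RUN in 1 library of sorted mouse prospermatogonia at E17.5, from 130000 cells, and an IgG library was made from the same kind of cells. The series concerns imprinting control regions and regions of low methylation in sperm, so the position of the mark at imprinted genes was a question of the design. The list held 135064 peaks covering 88.7 Mb. Median peak width was 572 bp, from 158 to 4441 bp, and the median fold enrichment was 6.0, from 1.61 to 32.6. Summit pileups had a median of 27 fragments, with 9 as the lowest and 316 as the highest. There were no replicates, so values are given with counting intervals.

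H3K4me3 peaks gathered at the ends of protein-coding genes. Of all peaks, 22985 (17%, Wilson interval 16.8 to 17.2) overlapped 1 kb either side of such an end, against 4.59% with the ends moved by 100 kb. At ends of genes over 10 kb long, coverage by peaks reached 33.4% at 400 bp inside the gene, against a mean of 4.06% at moved positions. Gene-end peaks were wider, with a median of 862 bp against 514 bp for distal peaks, and had a higher median pileup, 38 against 23 fragments. Their fold was lower, 5.39 against 6.32, beside a median local background of 6.18 against 2.39 fragments. The steps of that background have the size expected of counts within 10 kb in the same library, so the fold is read here against the surroundings of a peak. An IgG background with default caller windows was argued against by a test given further below. Whether IgG entered the calling in another way was left open.

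**Figure D1:**
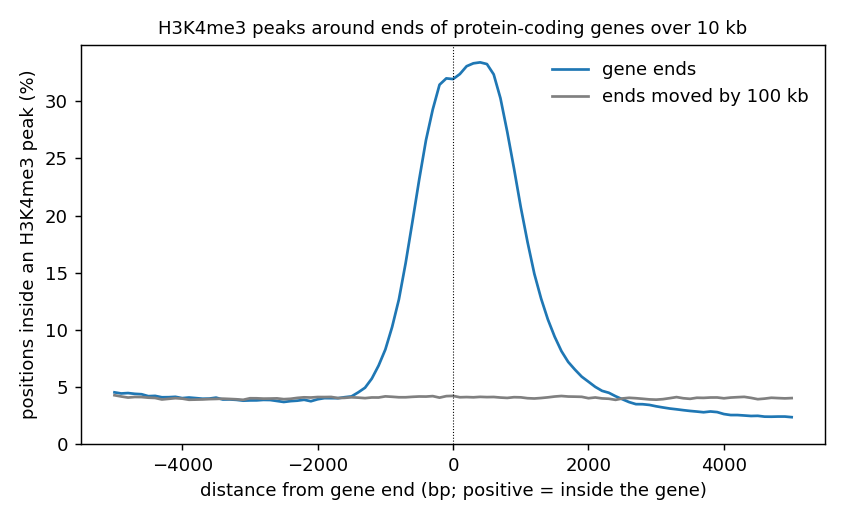
Share of positions inside an H3K4me3 peak (y axis, %) by distance in bp from the ends of 13961 protein-coding genes over 10 kb (x axis, positive inside the gene), with the same ends moved by 100 kb in grey. Coverage peaked at 33.4% 400 bp inside the gene, while moved positions stayed between 3.88% and 4.28%.

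Most protein-coding genes carried the mark at an end. Of 21887 genes, 16300 (74.5%, Wilson interval 73.9 to 75) were marked, against 23.9% with moved ends. One end alone was marked in 60.7% of genes and both ends in 13.8%. Long noncoding RNA genes were marked in 44.8%, against 20.6% with moved ends. The highest fold at a gene end was 32.6 (27.7 to 38.1) at Lars2, a mitochondrial leucyl-tRNA synthetase gene, on chromosome 9 from 123461833 to 123462215 in mm10. This peak was 383 bp wide with 155 fragments, and no IgG value or filter for multi-copy sequence was used to check it. The other end of Lars2 held a peak of 1352 bp with a fold of 8.45. Of the 89 peaks with a fold of at least 15, 2 were at a protein-coding gene end and 63 were distal. Asmt on the X chromosome followed with 16.8 (13.4 to 20.8). Olfr1465, Dynlt1b, Gm12695, Adtrp, Emp1, Mysm1, Akr1c20 and Gm46425 lay between 13.1 and 14.9.

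Genes of the male germ line were marked in most cases. In the germ cell identity list 17 of 20 genes were marked, at percentile 88.2 of matched random lists and 3.54 with a fold of at least 5, both within the central 95%. With ends moved by 100 kb 45% of this list met a peak. It was led by Dppa4 at a fold of 7.64, Tex101 at 7.60 and Mageb4 at 7.38. Nanos2, Nanos3 and Rhox5 were unmarked, and no peak overlapped these 3 genes. Of 21 spermatogonial genes 19 were marked, at percentile 94.1, led by Sohlh1 at 9.31 (6.46 to 13.0), Rarg and Dmrt1, while Dmrtb1 and Tspan8 were not. Inside Dmrtb1 lay 4 peaks, the widest of 1178 bp with 40 fragments, and inside Tspan8 3, the widest of 533 bp with 15. The spermatogonial percentile was 97.7 within 500 bp and 97.9 with the summit inside the window, above the central 95%, but 0.265 with a fold of at least 5, below it. The piRNA list, whose products silence transposons in germ cells, had 21 of 23 marked, led by Piwil4 at 9.84 (6.82 to 13.8), Tdrd12 at 9.20 and Gtsf1 at 9.01. Piwil2 and Fkbp6 were unmarked at their annotated ends, but Piwil2 held an internal peak of 1243 bp with 40 fragments and Fkbp6 held 2, the wider of 750 bp with 34 fragments. Median fold of the piRNA list stood at percentile 99.1 of matched random lists, and its marked share at percentile 90.1, or 97.9 without neighbouring gene ends. The fold is set against the surroundings of a peak, so a high percentile of fold need not mean more fragments. Piwil4, Tdrd12 and Gtsf1 had 32, 46 and 45 fragments, over backgrounds of 2.35, 4.11 and 4.11. Medians over all gene-end peaks were 38 and 6.18.

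Most meiotic genes were marked in these premeiotic cells, and 50% of the genes of sperm formation. In the meiosis list 26 of 28 genes were marked, led by Syce1 at 10.3 (7.80 to 13.5), Dmc1 at 8.56 and Majin at 8.53, and the median fold of 7.21 stood at percentile 99.95. As for the piRNA list, a high fold over the surroundings need not mean more fragments. The marked share of this list was at percentile 89.9 of matched lists, 99.2 of lists not matched and 64.5 with the 7 genes that had no neighbouring gene end. Spo11 and Stag3 were unmarked, each with internal peaks. Of 26 spermiogenesis genes 13 were marked, at percentile 0.410 of matched lists. Tnp1, which encodes a transition protein that replaces histones in spermatids, had a fold of 10.7 (7.78 to 14.3), ahead of Spaca1 at 8.78 and Ldhc at 8.43. Acrv1, Akap4 and Catsper1 were among the unmarked genes, and so were the protamine genes Prm1 and Prm2. Akap4 held 2 internal peaks, the wider of 1375 bp with a fold of 7.38, and no peak overlapped the other 4. With only the 9 spermiogenesis genes that had no other protein-coding gene end within 5000 bp, the percentile was 63.5, and with a fold of at least 5 it was 21.6.

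Pluripotency and developmental genes stood high among matched lists by share marked. Pluripotency genes were marked in 15 of 16 cases, at percentile 99.9, led by Zfp42 at 8.95 (6.58 to 11.9), Lefty2 at 8.46 and Tfcp2l1 at 7.86. The Zfp42 fold was at the end of lower coordinate, and a peak at its other end had 5.71 with 51 fragments. Lefty1 was unmarked at its ends but held 1 internal peak of 892 bp with 40 fragments. The percentile was 96.9 without matching, 93.2 within 500 bp and 91.2 with a fold of at least 5, all within the central 95%. Of 46 developmental transcription factor and signal genes 43 were marked (93.5%, Wilson interval 82.5 to 97.8), at percentile 100. With ends moved by 100 kb 41.3% of this list met a peak, against 23.9% of all protein-coding genes, and the matching does not cover this. Lhx2 led at 11.7 (8.54 to 15.6), with Tbx5 at 7.48 and Hoxb1 at 5.28, and En2, Hoxa9 and Sox1 were unmarked. The median fold of this list was 3.03, at percentile 9.64 of matched lists, within the central 95%. With peaks of a fold of at least 5, 8.70% of its members were marked and the percentile was 0.000, so the direction turned with that threshold.

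Genes of chromatin and cell division were mostly marked. DNA methylation genes were marked in 15 of 18 cases, at percentile 45, led by Dnmt3l at 7.57, Ctcfl at 7.11 and Dnmt3b at 7.07. Dnmt1 and Dnmt3a had no peak at an annotated end, although Dnmt3a held an internal peak of 1360 bp and Dnmt1 one of 1208 bp. Dnmt3c had no peak. Enzymes of H3K4 and H3K27 methylation were marked in 20 of 21 cases, led by Kmt2d at 8.60, Wdr5 at 7.16 and Ezh1 at 6.91. Their percentile was 93.8, against 99.1 of lists not matched, 75.7 with the summit inside the window, 73.9 within 500 bp and 7.35 with a fold of at least 5. Dpy30 was unmarked at its ends but held an internal peak of 1519 bp with a fold of 7.45 and 52 fragments. Cell cycle genes were marked in 19 of 20 cases, at percentile 98.7, led by E2f1 at 8.88, Cdk1 at 7.52 and Ccna2 at 7.35. The E2f1 fold was that of a peak outside the gene, and the other end of E2f1 held a peak with a fold of 6.14. Cdkn1a was unmarked at its ends but held 3 internal peaks, the widest of 923 bp with 41 fragments. Housekeeping genes were marked in 24 of 25 cases, at percentile 99.7, led by Gpi1 at 12.5 (8.96 to 17.1) and Psmb2 at 9.46, and Ywhaz was unmarked at its ends. With a fold of at least 5, the percentiles were 52.5 for cell cycle and 60.6 for housekeeping genes, and without neighbouring gene ends 95.3 and 94.3, all within the central 95%. Within 500 bp the housekeeping percentile was 97.2.

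Markers of other fetal testis cells were marked in part. Sertoli markers were marked in 12 of 17 cases, at percentile 41.2, led by Clu at 8.32, Dhh at 6.93 and Rhox8 at 6.89, with Amhr2, Gata4 and Nr5a1 unmarked at their ends. The Sertoli percentile was 5.10 with a fold of at least 5, but 82.3 within 2500 bp and 94.7 without neighbouring gene ends, all within the central 95%. Leydig and interstitial markers were marked in 9 of 15 cases, at percentile 6.19, or 0.440 with a fold of at least 5, led by Acta2 at 10.1 (7.31 to 13.6), Cyp11a1 at 9.90 and Lhcgr at 7.34. Cyp17a1, Hsd3b1 and Insl3, steroid and hormone genes of Leydig cells, had no peak. Endothelial and blood markers were marked in 10 of 17 cases, at percentile 10.1. That percentile was 2.07 with 200 bp shared, but 39.7 within 2500 bp and 41.9 with a fold of at least 5. The list was led by the globin genes Hbb-bt at 11.1 and Hbb-bs at 9.16 and by Tek at 8.63, with Adgre1, Cdh5 and Csf1r unmarked. Genes of other organs were marked in 10 of 25 cases, at percentile 0.00500, including Ins1 at 9.48, Actn2 at 8.10 and Apoa1 at 7.82. With ends moved by 100 kb 36% of this list met a peak, against the 40% marked. Alb, Cyp2e1 and Gcg were unmarked.

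**Figure D2:**
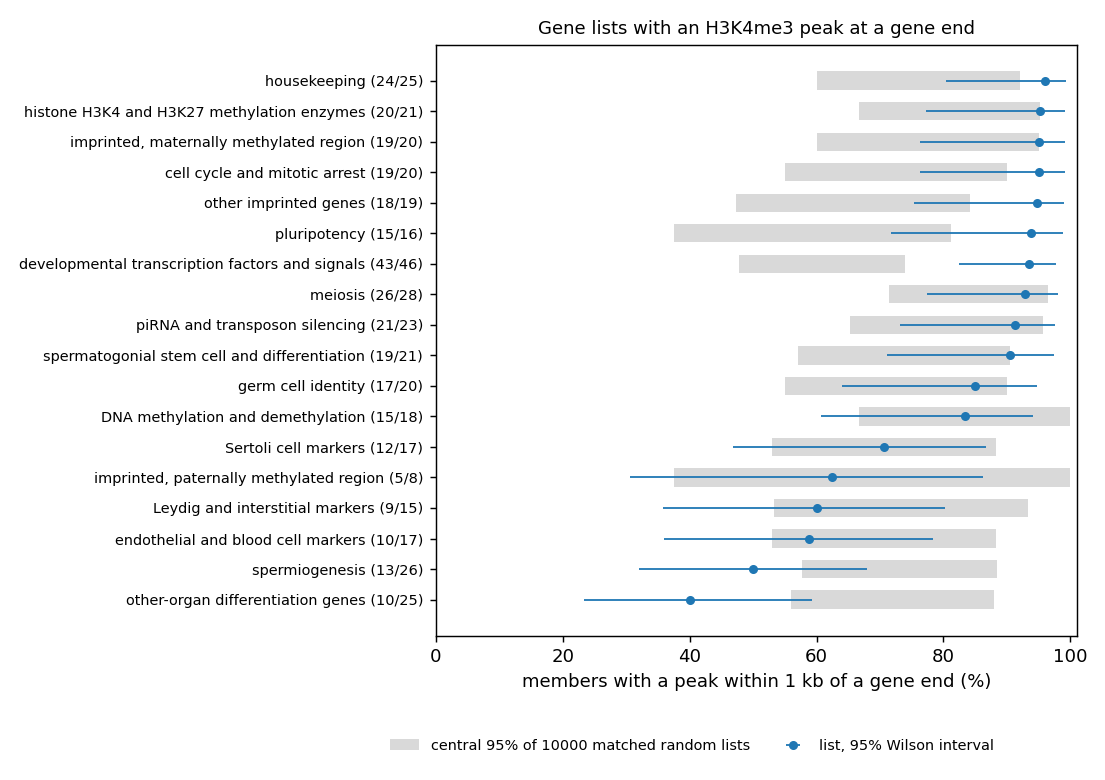
Share of members of 18 gene lists with a peak within 1 kb of a gene end (x axis, %), with 95% Wilson intervals in blue and the central 95% of 10000 matched random lists in grey. Developmental (93.5%), pluripotency (93.8%), other imprinted (94.7%), cell cycle (95%) and housekeeping genes (96%) lie above the grey range, and spermiogenesis (50%) and other-organ genes (40%) lie below it.

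Most imprinted genes carried H3K4me3 at one annotated end or both. Among genes with a maternally methylated control region at or near the promoter, 19 of 20 were marked (95%, Wilson interval 76.4 to 99.1), at percentile 98.2. This share equalled the upper limit of the central 95% of matched lists and did not exceed it. The percentile was 96.2 within 500 bp, 94.0 within 2500 bp, 88.4 with the summit inside the window and 32.5 with a fold of at least 5, all within the central 95%. On chromosome 7, the end of Kcnq1ot1 held a peak of 2161 bp from 143294791 to 143296951, with 50 fragments (a fold of 5.67, 4.24 to 7.44). Snurf held one of 2354 bp from 60002727 to 60005080 with 54 fragments. The same interval lay inside Snrpn, the only unmarked gene of that list, whose annotated extent runs to distant transcripts. A peak of 395 bp with 55 fragments lay inside Peg3 and reached the end windows of both Peg3 and Usp29. Peg10 and Sgce shared 1 peak of 755 bp and 1 of 610 bp. Impact had the highest fold, 9.11, and Nespas the lowest, 2.93. The fold of Impact was that of a peak from 12955402 to 12956312, and its other peaks, from 12971984 to 12974619, had folds of 4.34 to 4.75. The highest fold of Gnas, 6.41, lay from 174344824 to 174346532, and its other peaks had folds of 2.13 to 3.73. Without strand, these highest folds cannot be assigned to a promoter or control region. Nap1l5, Inpp5f, Gnas, Airn, Mcts2, Peg13, Nnat, Plagl1, Zrsr1, Grb10 and Mest lay between 3.43 and 7.29.

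In the list drawn up for a paternally methylated control region in the domain, 5 of 8 genes were marked, at percentile 25.5. Methylation was not measured here, and whether each of these regions is methylated in the germ line was not checked. H19 had a fold of 8.62 (6.25 to 11.6) from 142578171 to 142578697, Zdbf2 5.46, Dlk1 5.11, Rasgrf1 4.60 and Meg3 3.12. Igf2, Gpr1 and Rtl1 were unmarked, and 3 peaks lay inside Igf2, 10 inside Gpr1 and none inside Rtl1. Other imprinted genes were marked in 18 of 19 cases, at percentile 99.8, and 70.2 with a fold of at least 5. Zim1 was highest at 7.97, Copg2 followed at 7.15, and Magel2 and Dio3 were lowest at 2.76 and 2.74. Ndn, Klf14, Igf2r, Kcnq1, Mkrn3, Cd81, Slc22a18, Calcr, Ube3a, Ppp1r9a, Phlda2, Ascl2, Asb4 and Cdkn1c lay between 3.94 and 6.60. Ano1 was unmarked at its ends. The peak list does not separate the parental alleles.

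**Figure D3:**
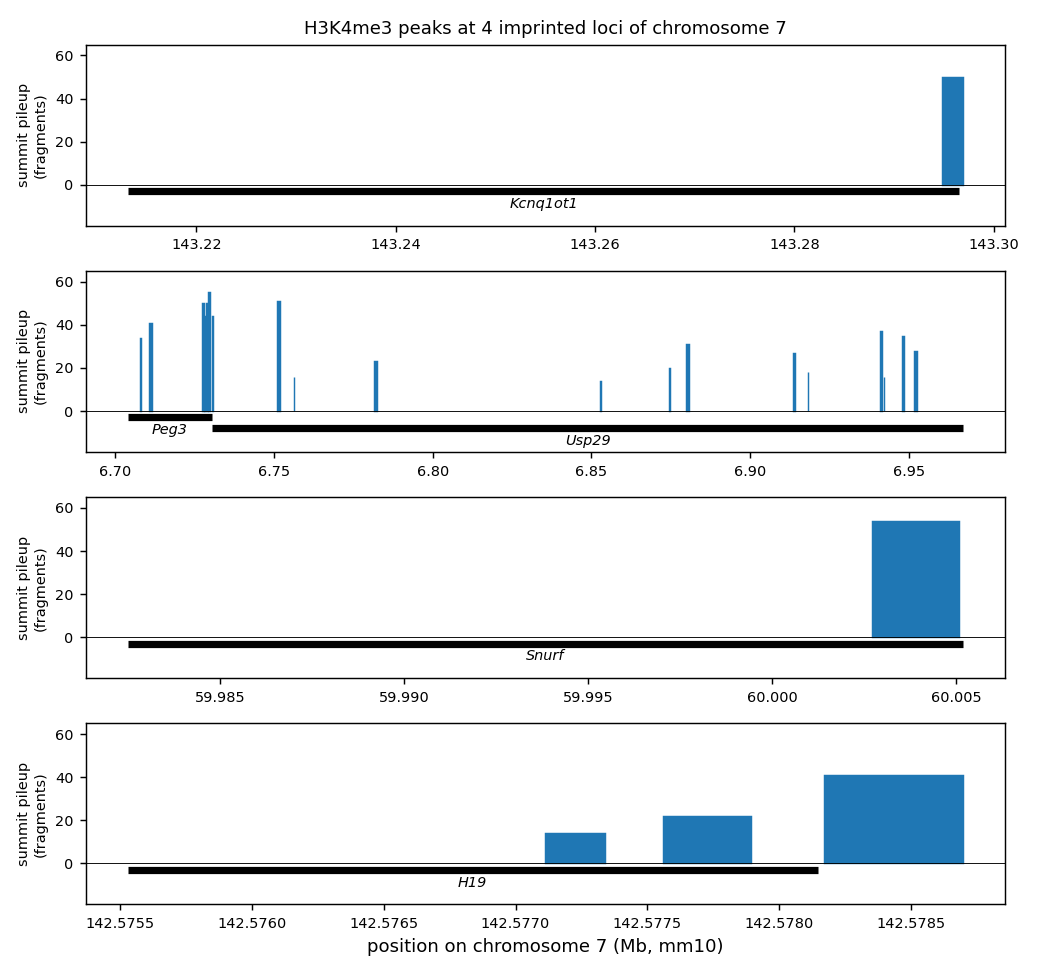
Peaks at Kcnq1ot1, Peg3 with Usp29, Snurf and H19 on chromosome 7, with position in Mb (mm10) on the x axis, summit pileup in fragments on the y axis, bars as wide as the peaks and gene extents in black. Summits reached 50 fragments at Kcnq1ot1, 55 at Peg3 and Usp29, 54 at Snurf and 41 at H19.

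X-linked genes were marked about as often as all autosomal genes and more often than matched autosomal sets, with lower pileups. Of 966 X-linked genes 75.7% were marked (Wilson interval 72.9 to 78.3), against 74.4% of autosomal genes. The X stood at percentile 100 among matched autosomal sets and at percentile 82.1 among sets not matched. Gene-end peaks of the X had a median of 26 fragments against 39 on autosomes, a ratio of 0.667 (0.667 to 0.692), and a median width of 614 against 880 bp. Median fold was 5.63 against 5.37. Of 256 Y-linked genes 71.9% were marked, against a mean of 46.5% in matched sets. With a summit pileup of at least 20 fragments 37.1% were marked, which turned the percentile from 100 to 1.6. The percentile of the 71.9% among sets not matched was 16.6. Peaks per Mb ranged from 43.4 to 56.4 on autosomes and were 47.4 on the X and 45.1 on the Y.

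**Figure D4:**
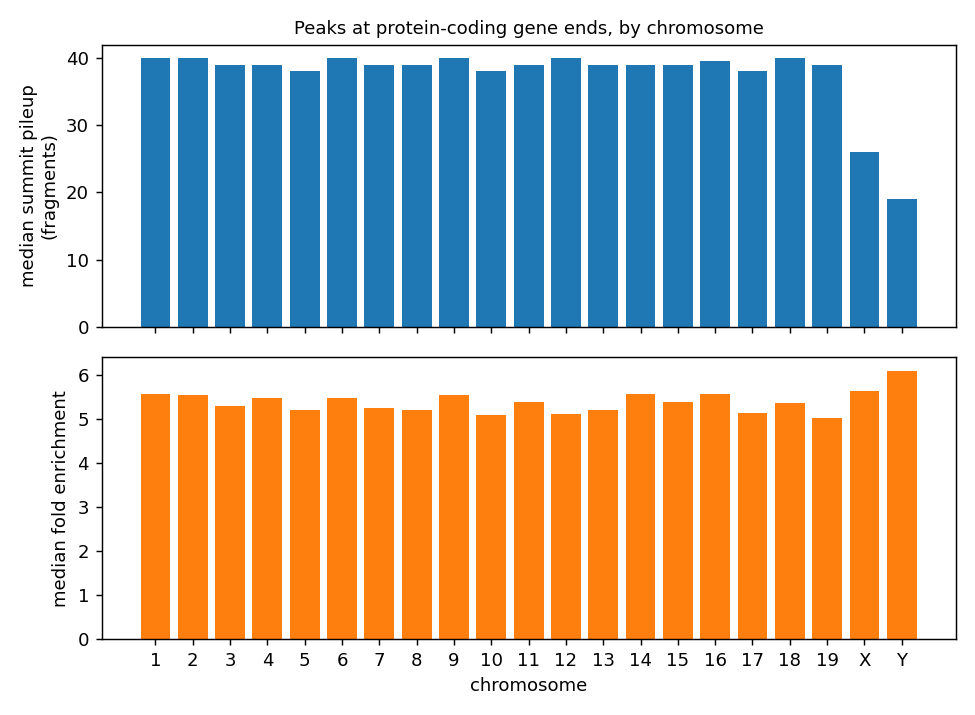
Median summit pileup in fragments (upper y axis) and median fold enrichment (lower y axis) of peaks at protein-coding gene ends, by chromosome (x axis). Medians of the pileup were 38 to 40 on autosomes, 26 on the X and 19 on the Y, while the fold was 5.63 on the X and 6.10 on the Y.

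Wide domains lay mostly at genes. Joining gave 105738 domains, and the widest 5% measured at least 2002 bp. Of 5289 wide domains 60.6% (Wilson interval 59.3 to 61.9) held a protein-coding gene end, against 9.34% of the others, and 35.5% with a join gap of 3000 bp. Among the 10 widest, Fst, which encodes follistatin, Adgrl2, Esrp1, Arid2, Gm38469 and Adamts1 had an end inside. The widest, 5559 bp on chromosome 17 from 39843056 to 39848614, held an annotated end of Rn18s-rs5 and none of a protein-coding gene. Domains on chromosome 9 from 3000046 to 3004765 and chromosome 1 from 24611638 to 24616078 also lay outside protein-coding genes. No filter for multi-copy sequence was applied here, and whether such sequence contributes to these widths was not tested. Of all protein-coding genes 16.8% had an end in a wide domain. The share was 47.6% of spermatogonial, 45% of cell cycle, 44.4% of DNA methylation and 38.1% of histone enzyme genes, and 10 of 20 genes of the maternally methylated list. In the germ cell list it was 35.0%, with Ddx4, Dazl, Sall4, Lin28a, Prdm1, Prdm14 and Trim71. Lower shares than that of all genes were found for Leydig (13.3%, 2 of 15), meiosis (10.7%, 3 of 28) and piRNA genes (8.70%, 2 of 23). The same held for spermiogenesis (7.69%, 2 of 26) and Sertoli genes (5.88%, 1 of 17). These counts are small, and the shares were not set against matched lists or tested against that of all genes. The median length covered by peaks at the fuller end followed this order only in part. It differed for meiosis, at matched percentile 94.7, spermatogonial genes at 56.6 and DNA methylation genes at 26.9. Cell cycle genes, at 96.2, and histone enzyme genes, higher still, were high by both measures. Leydig genes, at 1.615, and spermiogenesis genes, at 0.290, were low by both. Germ cell (69.4), maternally methylated (75.7), piRNA (62.4) and Sertoli genes (52.9) lay between. No endothelial, blood or other-organ list member was in a wide domain.

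Distal peaks made up 61.9% of the list, 83621 peaks. Of these 23.2% lay inside a protein-coding gene, against 29.3% after moving by 100 kb. The definition of a distal peak keeps summits away from gene ends and out of short genes, which may lower the first share. The highest distal fold, 31.5 with 104 fragments (85.0 to 126), lay inside Gphn on chromosome 12 from 78350861 to 78351169. Next came 30.9 on chromosome 8 from 15519782 to 15520120 and 30.6 on chromosome 3 from 56575405 to 56575816. Both lay outside protein-coding genes, 372602 bp from the nearest such gene end, of Csmd1, and 391847 bp from that of Nbea. A peak inside Chl1 on chromosome 6 from 103649041 to 103649354 had a fold of 28.0, and one inside Kctd16 on chromosome 18 from 40308000 to 40308404 had 27.8. These 5 peaks were 309 to 412 bp wide with 104 to 241 fragments, against a 95th percentile of 49 fragments over all peaks. No IgG value or filter for multi-copy sequence was used to check them. With a distance of 20000 bp, 52115 peaks were distal, and 52403 had at least 20 fragments at the standard distance.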

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

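Every alternative with a minimum pileup of 20 fragments or without genes that have another protein-coding gene end within 5000 bp was chosen after the data were seen. The −log10 q minimum of 2 and the whole list gave identical peaks and say nothing about stability. The alternative with only the 5′-most start site was not run, since no strand was used here. No paired analysis was possible because there was 1 library per antibody. The cause was not tested for any change below, except that a stricter peak set or a narrower window can only lower a share of genes. Depth limits the value of a single peak, since the median summit held 27 fragments.

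The share of peaks at gene ends, 17%, was 17.47% with −log10 q of at least 5, 14.5% with a fold of at least 5, 13.8% within 500 bp, 21.4% within 2500 bp, 15% with the summit inside, 15% with 200 bp shared and 22.5% with at least 20 fragments. The share of protein-coding genes, 74.5%, was in the same order 73.8%, 57.4%, 70.6%, 80.5%, 70.5%, 72.3% and 72.2%, and 65.9% without neighbouring gene ends.

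With a fold of at least 5, marked shares were 35.0% for germ cell identity, 28.6% spermatogonial, 62.5% pluripotency, 55.6% DNA methylation, 52.4% histone enzymes, 60% cell cycle, 35.3% Sertoli, 26.7% Leydig, 8.70% developmental, 55.0% maternally methylated, 57.9% other imprinted and 60% housekeeping genes. It was 53.2% over the imprinted lists together, 63.3% on the X and 60.5% on the Y. Percentiles with that fold were 3.54 germ cell identity (from 88.2), 0.265 spermatogonial, 91.2 pluripotency, 96.9 piRNA, 16.6 DNA methylation, 7.35 histone enzymes (from 93.8), 52.5 cell cycle, 96.1 meiosis, 21.6 spermiogenesis, 5.10 Sertoli (from 41.2), 0.440 Leydig, 41.9 endothelial and blood, 0.000 developmental (from 100), 32.5 maternally methylated, 12.3 paternally methylated, 70.2 other imprinted, 60.6 housekeeping and 0.180 other-organ genes.

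Within 2500 bp, shares were 100% for pluripotency and cell cycle, 88.2% Sertoli, 97.8% developmental, 87.5% paternally methylated and 80.2% X-linked genes, and the maternally methylated percentile was 94.0. Within 500 bp, shares were 80.4% developmental, 72.5% X and 51.2% Y, and percentiles were 97.7 spermatogonial, 93.2 pluripotency, 96.2 maternally methylated and 97.2 housekeeping. With the summit inside, percentiles were 97.9 spermatogonial and 88.4 maternally methylated, and the Y share was 56.3%. With 200 bp shared, the Y share was 55.5% and the endothelial and blood percentile 2.07. Without neighbouring gene ends, shares were 100% for pluripotency, piRNA, histone enzymes and maternally methylated genes and 90.0% for Sertoli genes, and percentiles were 97.9 piRNA, 95.3 cell cycle, 63.5 spermiogenesis and 94.3 housekeeping. Without matching, percentiles were 96.9 pluripotency, 99.1 histone enzymes, 99.2 meiosis, 82.1 X and 16.6 Y. With at least 20 fragments, shares were 71.0% on the X and 37.1% on the Y, with a Y percentile of 1.6 (from 100).

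With −log10 q of at least 5, median width was 623 bp and median fold 6.18. The share of wide domains at a gene end, 60.6%, was 58.1% with a fold of at least 5, 63.7% with at least 20 fragments, 53.4% with no joining and 35.5% with a 3000 bp gap. Distal peaks numbered 52403 with at least 20 fragments and 52115 at 20000 bp.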

Other observations

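Gene families, chosen after the data were seen, differed in how often an end was marked. Of 1110 olfactory receptor genes 20.0% were marked, against 20.9% with moved ends, and of 355 vomeronasal receptor genes 7.89%, against 20.0%. By contrast, 98.5% of 67 clustered histone genes, 98.7% of 77 ribosomal protein genes and 92.9% of 397 Zfp genes were marked, against 23.9%, 28.6% and 29.5% with moved ends. Of 39 clustered Hox genes 89.7% were marked, 43.6% at both ends, against 38.5% with ends moved by 100 kb one way and 51.3% the other way. Of 408 tRNA genes 65% were marked, against 23.8% with moved ends, but of the 139 over 20 kb from any protein-coding gene end 43.9% (Wilson interval 35.9 to 52.2), against 25.2%. Midpoints of 5804 pseudogenes over 20 kb from any protein-coding gene end lay near a peak in 33.4% (Wilson interval 32.2 to 34.6), against 11.9% after moving by 100 kb.

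All tests in the paragraphs that follow were chosen after the results were seen. Fold enrichment was lower at gene-end peaks than at distal peaks. Fewer fragments at gene ends were argued against by the ratio of median pileups, 1.65 (1.65 to 1.70). An IgG background with default caller windows was argued against by the share of backgrounds at multiples of 10 steps, 9.94%, since 1 kb windows would fill those multiples. A candidate explanation is that the background was counted in the H3K4me3 library within 10 kb: its rank correlation with called peak area within that span was 0.898 across peaks, which are not independent replicates. Under that hypothesis a fold threshold removes genes in broadly marked regions first, and a biological explanation was not tested.

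Summit pileups were lower on the X. A single X copy may account for this, and so might less H3K4me3 on the X. The ratio of X to autosomes was 0.667 for pileup and 0.564 for the background, both counted in the same library. For the Y these ratios were 0.487 and 0.334, with the median Y background at the floor of 2.11 fragments. The 2 explanations given for the X cannot be told apart, because no input or IgG value was used here.

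Most peaks lay away from annotated gene ends. Chance calls near the threshold were argued against under the Poisson model of the peak caller, since 59.3% of distal peaks had a −log10 q of at least 10. That q assumes Poisson counts around the local background, so it cannot decide on fragments more clustered than this. A background above 3 times the floor was found at 4.82% of distal peaks and 47.2% of gene-end peaks. That argues against collapsed repeat arrays long enough to raise the 10 kb background as the cause of most distal peaks. Short collapsed repeats would hardly move a 10 kb background, so this share cannot decide on them and they stay open. Cutting that an IgG library would also show stays open and may contribute: 41.6% of distal peaks were at the floor, which decides nothing, and no IgG value was used here. Repeats with single reads placed apart also stay open, and no biological explanation was tested.

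The highest recovered background, 122 fragments, was at a peak on chromosome 9 from 3020804 to 3021135, with a pileup of 290 and a fold of 2.37. A single peak of 4441 bp on chromosome 1 from 24611638 to 24616078 was the widest in the list and had a fold of 2.84. Its background was 40.6 fragments, and no filter for multi-copy sequence was applied here.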
